A study of Homo sapiens with 4 samples.

How the data were processed

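Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was analysed for 4 libraries from human CD133-positive umbilical cord blood cells, which are hematopoietic stem and progenitor cells. Per the labels' protocols, the cells were expanded in culture for 10 to 11 days, selected again for CD133, and were 75 to 90% positive for both CD34 and CD133. They were cross-linked for 20 min with formaldehyde, and the same number of cells was used per immunoprecipitation. One library was made with an antibody against H3K27me3 and one with an antibody against H3K79me2. The other two hold runs 1 and 2 with an antibody against total RNA polymerase II (RNA Pol II). Per the labels, chromatin fragments averaged 1000 bp for H3K27me3 and RNA Pol II and 500 bp for H3K79me2, and libraries were amplified with 18 PCR cycles. A difference between H3K79me2 and the other libraries may therefore include a difference in fragment size.

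The deposited files list the location of each aligned read, with a minus sign for the minus strand, and hold no counts per gene or peak. Reads were aligned with Bowtie against the human build hg18, per the file headers, with the options -e 70, -k 2, -m 2, -n 2, -l 36 and --best. The Bowtie version is not given in the sources used here. Each deposited file separates its reads into a first and a second category, whose meaning is not given in the sources used here, and repeated positions were kept in it. Per the series' design text, a whole cell extract served as the authors' background. No such library was analysed here, so each library was compared with its own mean, and sequence that is over-represented in any library counts as enriched.

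The first category was used, on the 22 autosomes. Sex chromosomes were left out throughout. At most 1 read was kept per position and strand, and for RNA Pol II this was done over both runs together, because the labels give both runs the same biological replicate number. Keeping 1 read removes PCR copies and also real coincidences at the highest positions. The highest mitochondrial positions on both strands fitted the leftmost base of a read, and a read length of 36 bp was assumed from the aligner option. Each read was moved 100 bp towards its 3′ end and counted in 2 kb bins.

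A bin was usable if any library had a read in it, which held for 1260953 of 1433453 bins. A bin was called enriched when a Poisson test against the library's mean gave a Benjamini-Hochberg adjusted p under 0.01 and the bin held at least 3 times the mean. Enriched bins at most 1 bin apart were merged into regions. Overlaps of enriched bins were set against the number expected from independent lists and against 100 circular shifts of one set along each chromosome. The permutation p from these shifts is two-sided, and the smallest they can give is 0.0198. Levels are mean reads per bin over the library's mean over usable bins, with 95% intervals from 1000 resamplings of 10 Mb blocks of the genome. Shares carry 95% Wilson intervals and read counts of single regions 95% exact Poisson intervals. These cover counting error only. With 1 sample per mark there is no replicate check, and tests compare bins within a library and not conditions.

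Regions to be named were chosen by a rule set before the data were examined. They are the 10 regions with the highest bin for each mark, past the threshold in both runs for RNA Pol II, and the widest 10 regions of H3K27me3 and of H3K79me2. Because most of the highest regions were enriched in all 3 immunoprecipitations, lists without such regions were added after their values were seen. Results for genes, gene lists and the ratio of promoter to gene body had been planned on condition that an annotation of hg18 was at hand. The gene table used here was of GRCh38, so coordinates were not matched to it and positions are given in hg18 without gene names.

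Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The calling of enriched bins was tested on simulated data with 1260953 bins per library and 200 bins raised at each level. Bins raised 12-fold were recovered in 100% of cases for H3K27me3 and for H3K79me2 and in 95.5% for RNA Pol II. At 5-fold the recovery was 27%, 50.5% and 14%, in the same order, with 3, 2 and 2 false calls per simulated library. The simulated counts were Poisson, as the test assumes, so few false calls had to result. In the real libraries the variance of reads per bin over their mean was 2.24, 5.97 and 1.67, in the same order. The false calls therefore do not measure the error among the real enriched bins. RNA Pol II bins raised 8-fold were recovered in 55% of cases. Alternatives covered bin width, fold and p thresholds, repeated reads, the shift, the background, thinning all libraries to 1246553 reads, single runs the definition of overlap and, added after the data were seen, leaving out bins near long runs without reads.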

Results

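The 4 libraries map a repressive histone mark, a mark of transcribed chromatin and the polymerase itself in expanded cord blood stem and progenitor cells. H3K27me3 is deposited by Polycomb repressive complexes. H3K79me2 is deposited by DOT1L and lies over the start of transcribed units. The H3K27me3 library held 7161787 autosomal reads at 2531066 distinct positions, and the H3K79me2 library 5797056 reads at 3423182 positions. RNA Pol II run 1 held 3963867 reads at 1407746 positions and run 2 held 3132270 reads at 1246553 positions. Both runs together covered 1641057 distinct positions, with 4.32 reads per position, against 2.83 for H3K27me3 and 1.69 for H3K79me2. The mean number of distinct reads per usable 2 kb bin was 2.01 for H3K27me3, 2.71 for H3K79me2 and 1.30 for RNA Pol II. An enriched bin held at least 10, 11 and 10 reads, in that order.

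With 1 read kept per position, H3K79me2 was enriched in more bins than H3K27me3 or RNA Pol II. With all reads as deposited the order changed, with 105553 bins for RNA Pol II and 78953 for H3K79me2. In the designed setting H3K79me2 was enriched in 50920 bins, 4.04% of those usable, which made 13574 regions over 102 Mb. These bins held 27.1% (95% interval 27.1 to 27.2) of the library's distinct reads. The median region was 4 kb wide and 43.9% of regions were a single bin, while 3379 were at least 10 kb wide and 263 at least 50 kb. The widest spanned 242 kb on chromosome 7 (92080001 to 92322000, hg18), with 10.3 times the library mean (9.95 to 10.6) over 3380 reads. There, RNA Pol II was 1.91 times its mean (1.70 to 2.13) and H3K27me3 0.725 times (0.622 to 0.840). The next widest covered 240 kb of chromosome 12 (11692001 to 11932000), with H3K79me2 at 10.3 times, RNA Pol II at 1.505 times and H3K27me3 at 0.681 times their means. A 184 kb region on chromosome 3 (153434001 to 153618000) was among the 10 widest and also among the 10 highest, with H3K79me2 at 12.7 times its mean (12.3 to 13.2). Across the 10 widest regions RNA Pol II ranged from 1.14 to 1.91 times its mean. The count of enriched bins fell to 5661 against the mean of the surrounding 50 kb, a background that wide regions raise.

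H3K27me3 was enriched in 11838 bins, 0.939% of those usable, in 6303 regions over 23.7 Mb. These bins held 6.45% (6.42 to 6.48) of its distinct reads. As called, most regions were narrow, with 63.9% of them a single bin, while 469 were at least 10 kb wide and 7 at least 50 kb. These widths depend on what a bin needs to pass, at least 10 reads. Of simulated bins raised 5-fold, 27% were recovered. Outside the edges of regions of at least 10 kb, H3K27me3 was still 2.77 times its mean at 1 kb and 1.77 times at 29 kb. The widest region was 136 kb on chromosome 12 (52606001 to 52742000), where H3K27me3 was 8.06 times its mean (7.59 to 8.55). H3K79me2 was 0.330 times its mean there (0.253 to 0.424) and RNA Pol II 0.859 times (0.677 to 1.07). A region of 104 kb on chromosome 2 (176636001 to 176740000) had H3K27me3 at 8.27 times and H3K79me2 at 0.333 times their means. Others among the 10 widest lay on chromosome 17 (44018001 to 44080000), chromosome 5 (92928001 to 92986000) and chromosome 7 (27186001 to 27234000). The last of these had the highest RNA Pol II of the 10, 1.47 times the mean (1.08 to 1.96). Over the 10 widest, H3K79me2 ranged from 0.236 to 0.594 times its mean. With each region's 95% interval, all 10 lay below 1 for H3K79me2. The count of bins was 1611 against the surrounding 50 kb.

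**Figure D1:**
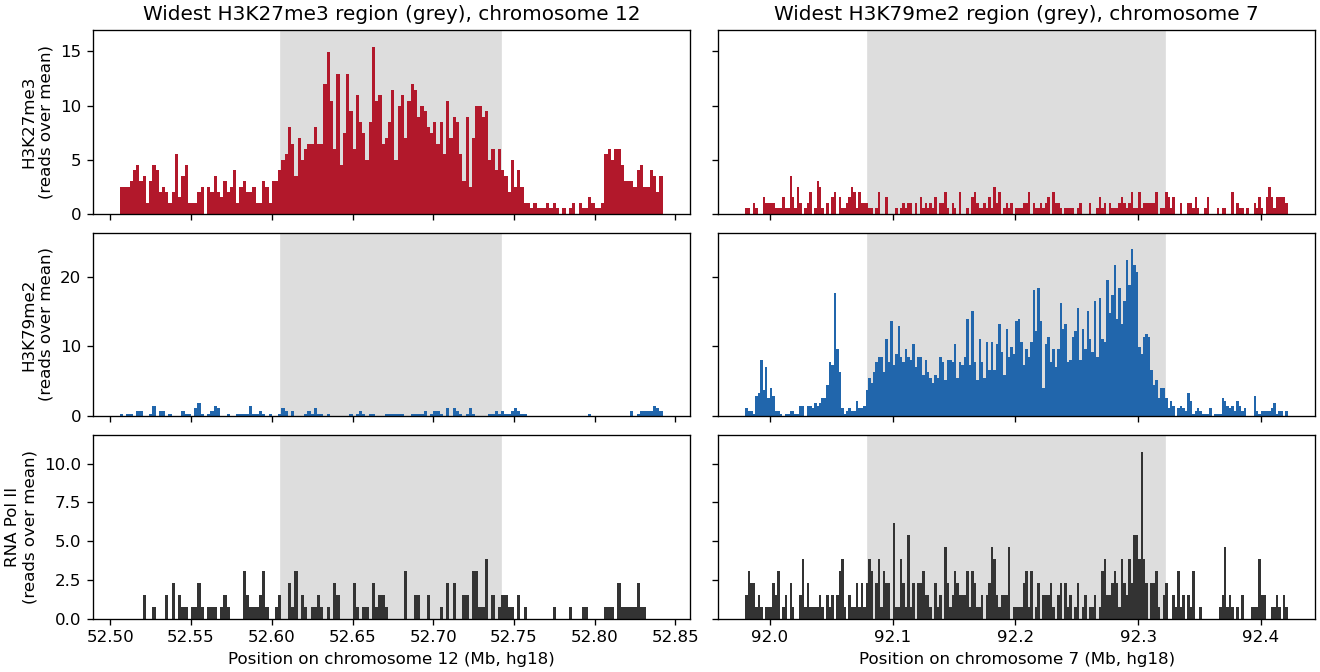
Reads per 2 kb bin over the library's mean along the widest H3K27me3 region (left, chromosome 12) and the widest H3K79me2 region (right, chromosome 7), with 100 kb on either side; grey marks the region, bars are single bins and the y axis is shared within a row. H3K27me3 averaged 8.06 times its mean in the region on the left, where H3K79me2 averaged 0.330 times, and H3K79me2 averaged 10.3 times its mean in the region on the right.

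As called, RNA Pol II was enriched in few and narrow places. It passed in 576 bins, 0.0457% of those usable, in 417 regions, of which 83.2% were a single bin. The bins held 0.651% (0.639 to 0.663) of the distinct reads. Each run called alone gave 613 and 488 bins, and 410 were shared, 84.0% (80.5 to 87.0) of the smaller list. Read counts per bin correlated between the runs with Pearson's r of 0.849 and Spearman's rho of 0.788, across bins, which are not independent replicates. Of the distinct positions of run 2, 81.3% (81.2 to 81.4) also occurred in run 1, and the labels give both runs the same biological replicate number, so they were counted as 1 sample. The number of enriched bins was 105553 with all reads as deposited.

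The 10 highest regions of RNA Pol II, and the 10 highest of H3K27me3, all held a bin enriched in all 3 immunoprecipitations, as did 6 of the 10 highest of H3K79me2. There were 80 such bins. The highest single bin for each mark lay on chromosome 1 (121184001 to 121188000). It reached 183.8 times the mean for H3K27me3, 118.6 times for H3K79me2 and 340.4 times for RNA Pol II. Averaged over that 4 kb region, they were 98.1, 63.0 and 187.1 times, in the same order. A region of 8 kb on chromosome 6 (58880001 to 58888000) averaged 50.4, 37.3 and 109.3 times, in the same order. Its part called for H3K79me2, 4 kb wide (58884001 to 58888000), averaged 95.7, 72.4 and 208.2 times. Overlaps are therefore given with and without these 80 bins. Levels in enriched bins, levels by the strength of a mark and profiles are given without them only. This choice was made after they were seen.

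Among regions without such bins, the highest single RNA Pol II bin, at 36.1 times the mean, was on chromosome 14 (74814001 to 74820000). The whole region was at 26.1 times the mean (21.3 to 31.7), with H3K27me3 at 5.15 times (3.50 to 7.31) and H3K79me2 at 0.614 times (0.199 to 1.43). On chromosome 11 (65022001 to 65032000) RNA Pol II was 24.3 times and H3K79me2 14.9 times the mean. On chromosome 19 (18246001 to 18254000) they were 18.6 and 5.71 times, and on chromosome 10 (3806001 to 3818000) 13.7 and 7.31 times. On chromosome 6 (26342001 to 26344000) RNA Pol II reached 33.0 times its mean (23.9 to 44.5) over 43 reads, with H3K79me2 at 2.95 times (1.27 to 5.81) over 8 reads. The highest H3K79me2 bins outside the shared ones lay on chromosome 7 (26196001 to 26218000), 28.7 times the mean, with RNA Pol II at 3.63 times over the region. The 3 highest H3K27me3 regions outside the shared ones were single bins on chromosome 11 (84872001 to 84874000), chromosome 17 (30502001 to 30504000) and chromosome 5 (71182001 to 71184000). H3K27me3 there was 30.9, 28.9 and 22.9 times and RNA Pol II 19.2, 22.3 and 21.5 times the mean. All 3 are among the 38 bins enriched for H3K27me3 and RNA Pol II but not for H3K79me2. Reads from repeated sequence may account for those 38 bins, as described under the other observations. The next highest H3K27me3 region was 32 kb on chromosome 2 (172648001 to 172680000) at 11.1 times the mean (9.96 to 12.3). RNA Pol II there was at 0.960 times (0.587 to 1.48).

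H3K27me3 and H3K79me2 shared fewer bins than expected. They shared 121 bins where 478 were expected from independent lists, a ratio of 0.253, and the 100 circular shifts gave 418 to 639 (permutation p = 0.0198, the smallest they can give). The ratio was 0.126, with 56 shared bins, when bins within 1 Mb of a run of at least 100 kb without reads were left out. Without the 80 bins the overlap was 41 against 474, a ratio of 0.0865, which had to be lower because those bins are by definition part of the overlap. In H3K27me3 bins, H3K79me2 was 0.503 times its mean (0.486 to 0.524). That mean includes the enriched H3K79me2 bins, which held 27.1% of its distinct reads in 4.04% of usable bins. A level below 1 may therefore in part reflect the absence of such bins. In H3K79me2 bins, H3K27me3 was 0.754 times its mean (0.741 to 0.767). H3K79me2 was 1.05 times its mean in bins with H3K27me3 under its mean, 0.656 times at 3 to 5 times the H3K27me3 mean 0.415 times (0.390 to 0.441) at 8 to 12 times and 0.493 times (0.416 to 0.580) in the 258 bins at 12 times or more. H3K27me3 was 0.743 times its mean at 5 to 8 times the H3K79me2 mean and 0.930 times (0.880 to 0.984) at 16 times or more. With all bins kept, the ratio was 1.04 (permutation p = 0.990) at an unadjusted p under 1e-09, with 49 shared bins, of which all but 1 were among the 80. It was 4.29 (permutation p = 0.0198) against the surrounding 50 kb, with 31 shared bins, all among the 80. With the bins near runs without reads left out, these settings gave 0.207 (permutation p = 0.0198) with 9 shared bins and 1.08 (permutation p = 1) with 7.

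RNA Pol II lay with H3K79me2. The 2 shared 275 bins where 23.3 were expected, a ratio of 11.8, against 11 to 41 in the shifts (permutation p = 0.0198). Without the 80 bins it was 195 against 20.0, a ratio of 9.75. The ratio was 1.76 with all reads as deposited and 4.02 with 1 read per position in each run and the runs summed. Mean RNA Pol II rose with H3K79me2, from 0.927 times its mean (0.923 to 0.931) in bins with H3K79me2 under its mean to 1.27 at 3 to 5 times, 1.60 at 8 to 12 times and 2.40 (2.12 to 2.82) at 16 times or more, where there were 631 bins. In H3K79me2 bins it was 1.43 times its mean (1.41 to 1.45), and in RNA Pol II bins H3K79me2 was 4.34 times its mean (3.85 to 4.91). Of 375 RNA Pol II regions without a shared bin, 280 had their highest bin within 10 kb of H3K79me2, 74.7% (70.03 to 78.8), against 33 to 65 in the shifts.

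**Figure D2:**
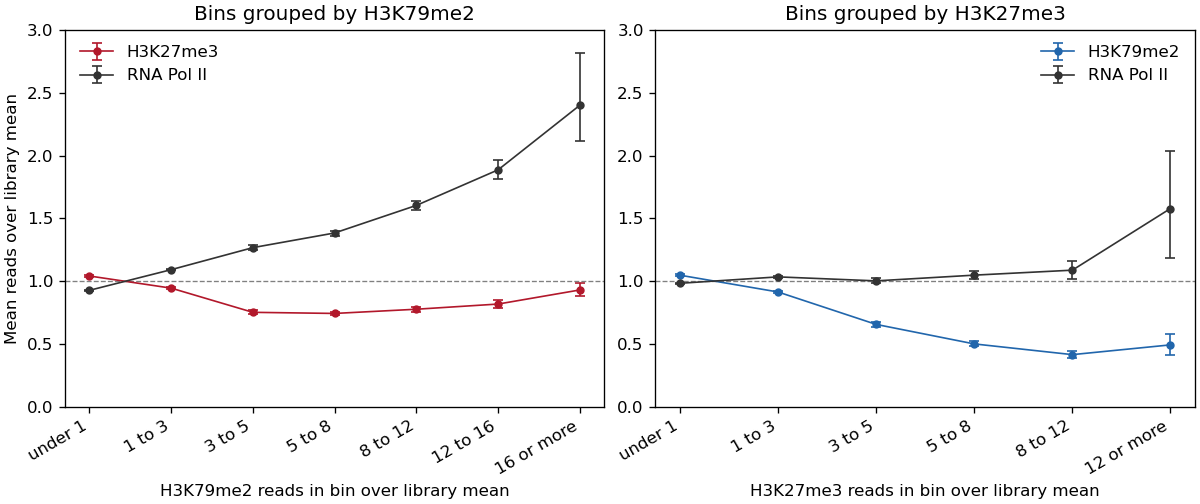
Mean reads per 2 kb bin over the library's mean (y axis) in bins grouped by their H3K79me2 (left) or H3K27me3 (right) reads over the mean (x axis), without the bins enriched in all 3; bars are 95% intervals from resampled 10 Mb blocks. RNA Pol II goes from 0.927 to 2.40 with rising H3K79me2, and H3K79me2 from 1.05 to 0.415 at 8 to 12 times the H3K27me3 mean and 0.493 at 12 times or more.

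At the edges of the 3369 H3K79me2 regions of at least 10 kb, RNA Pol II was 1.07 ± 0.013 (SE) times its mean at 3 kb outside, 1.58 ± 0.019 in the first 2 kb inside and 1.37 ± 0.018 at 9 kb inside. H3K27me3 was 0.783 ± 0.0088 in the first 2 kb inside, its highest, and 0.699 ± 0.0087 at 3 kb outside, its lowest. At 9 kb inside it was 0.717 ± 0.0087 and at 29 kb outside 0.757 ± 0.0099. At the edges of 463 H3K27me3 regions of at least 10 kb, H3K79me2 was 0.689 ± 0.038 at 29 kb outside and 0.436 ± 0.021 at 5 kb inside. RNA Pol II there was 1.08 ± 0.038 in the first 2 kb inside, its highest, 0.963 ± 0.042 at 5 kb inside and 0.897 ± 0.033 at 29 kb outside. These errors are over regions of 1 sample. Both edges of each region were averaged. In a 10 kb region, the bin 9 kb inside 1 edge is the first bin inside the other. The values inside are therefore not those of the interior alone.

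**Figure D3:**
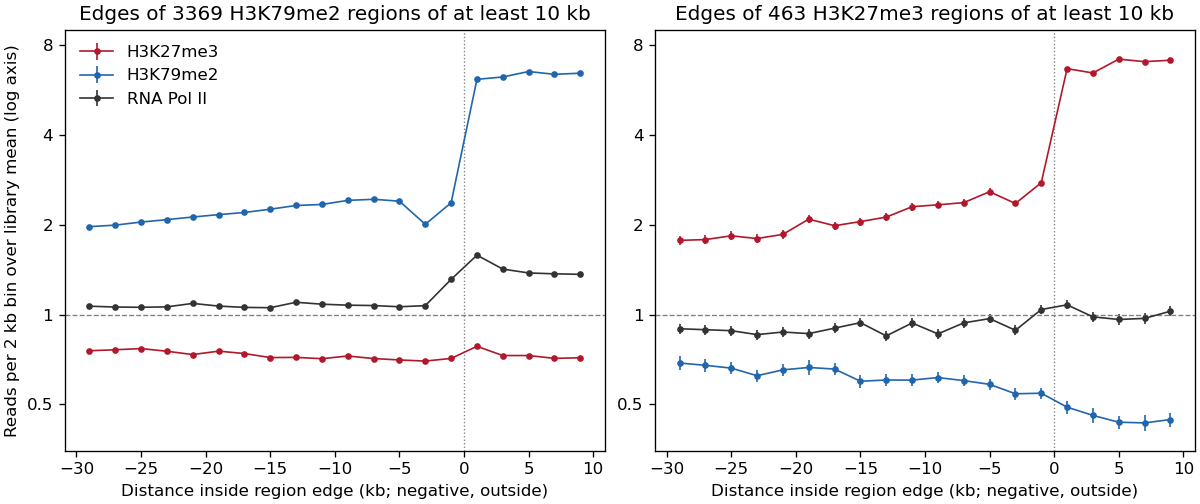
Mean reads per 2 kb bin over the library's mean (log axis) by distance from the edges of H3K79me2 (left) and H3K27me3 (right) regions of at least 10 kb, with SE over regions; the dotted line is the edge. RNA Pol II is highest, at 1.58, in the first 2 kb inside H3K79me2 regions, and H3K79me2 stays below 0.7 on both sides of H3K27me3 edges.

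H3K27me3 and RNA Pol II shared 118 bins where 5.41 were expected, a ratio of 21.8 (permutation p = 0.0198), but 80 of these were also enriched for H3K79me2. Without them the overlap was 38 against 4.63, a ratio of 8.22, with 0 to 15 in the shifts. Mean RNA Pol II in H3K27me3 bins was 1.05 times its mean (1.02 to 1.08). In the 496 RNA Pol II bins outside the 80, which include these 38, H3K27me3 was 1.96 times its mean (1.61 to 2.31). RNA Pol II was 1.58 times its mean (1.18 to 2.04) in the 258 bins with H3K27me3 at 12 times or more, a mean carried by few of them. The 225 of these bins without positions of the second read category, a split made after the value was seen, gave 1.09 times (0.884 to 1.37). Within 10 kb of H3K27me3 lay 38 of the 375 RNA Pol II regions, 10.1% (7.47 to 13.6), against 10 to 32 in the shifts, and 72 regions were near neither mark. The overlap ratio was 1.27 with all reads as deposited and 2.90 with 1 read per position in each run and the runs summed.

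**Figure D4:**
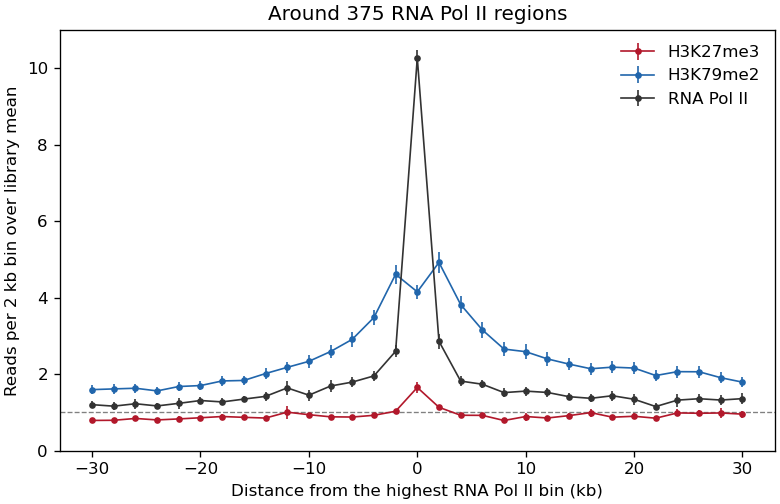
Mean reads per 2 kb bin over the library's mean by distance from the highest bin of 375 RNA Pol II regions without a bin enriched in all 3, with SE over regions. H3K79me2 is 4.15 at the highest RNA Pol II bin and 4.61 and 4.92 in the bins beside it, and H3K27me3 is 1.65 at that bin.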

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

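Both tests of the shared read positions and the 3 tests of the bins enriched in all 3 immunoprecipitations were chosen after the result was seen. The tests of the few RNA Pol II bins were set before their own results, though the 500 bp bins were not a planned setting. Reads outside the autosomes and the first category stood above what a count of 0 allows, with no control library to set them against. Any read set of this size would pass that limit, so the values are given as a description. Mitochondrial reads made up 0.0133% of autosomal and mitochondrial reads for H3K27me3, 0.00567% for H3K79me2, 0.0977% for RNA Pol II run 1 and 0.0959% for run 2. The second read category made up 7.48% of autosomal read lines for H3K27me3, 7.16% for H3K79me2, 7.74% for RNA Pol II run 1 and 7.73% for run 2.

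The 2 RNA Pol II runs shared 81.3% of the positions of run 2. Positions that every library draws are argued against, since libraries of different marks shared at most 0.419%. The same amplified library sequenced in both runs is a candidate explanation, with the 81.3% shared. No biological explanation was tested, as the labels give both runs the same biological replicate number.

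The 80 bins enriched in all 3 immunoprecipitations held the highest values of every mark. Of them, 75.0% (64.5 to 83.2) lay within 1 Mb of a run of at least 100 kb without reads, against 4.02% of other H3K79me2 bins. Many of the 80 bins lie side by side, so the interval, which treats them as independent, understates the uncertainty. With such a share, copies of a sequence that are missing from or collapsed in the build may be the source of the 80 bins. The 80 bins also held a mean of 126.8 positions of the second read category. In other H3K79me2 bins the mean was 0.614 and in all usable bins 0.458. If that category holds reads that align to more than 1 place, which is assumed, repeated sequence within the build may also contribute. The 2 sources were not told apart. PCR copies at the same position and strand were removed before the bins were called, so such copies cannot add to their counts. The 80 bins were 30.99 times the 2.58 expected from independent lists, against 0 to 8 in 100 circular shifts. This test was set for PCR duplicates arising separately in each library. It shows that the lists coincide, and with copies already removed it does not measure PCR duplicates. A count set for the same explanation, 80 bins with 1 read per position and strand against 477 with all reads, fell between its bounds and decides nothing, since it restates how the bins were defined. No biological explanation was tested, and no whole cell extract was used here to measure these bins without an antibody.

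RNA Pol II gave 576 enriched bins, against 50920 for H3K79me2. Fewer distinct reads are argued against as the whole cause, since H3K79me2 thinned to the reads of RNA Pol II run 2 still gave 22304 bins. The test of enrichment narrower than the bins cannot decide, although 500 bp bins gave 287 regions where 2 kb bins gave 417. Per the labels, RNA Pol II chromatin fragments averaged 1000 bp, wider than such a bin. A smaller bin also holds fewer reads, so fewer can pass. A weaker immunoprecipitation and a real difference in the extent of the polymerase and the mark stay open, as untested.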

How the results depend on the processing

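Settings that leave out the bins enriched in all 3, leave out bins near runs without reads, use both read categories, use 500 bp bins, or keep 1 read per position in each run were chosen after seeing the data. RNA Pol II overlapped H3K27me3 and H3K79me2 above expectation under all 17 alternatives each, with ratios of 1.27 to 167 and 1.76 to 70.6. The threshold of 2 times the mean changed no call and so could not alter a ratio, and single runs are parts of the same sample. Without the bins enriched in all 3, the ratios were 8.22 and 9.75. The overlap of H3K27me3 and H3K79me2 was below expectation under 15 of 18, of which 3 leave out the bins enriched in all 3 and so had to lower it. It reversed to 4.29 against the surrounding 50 kb. It did not differ from the shifts at an unadjusted p under 1e-09, with 1.04 (permutation p = 0.990), nor against the surrounding 50 kb without bins near runs without reads, with 1.08 (permutation p = 1). The stricter p without those bins gave 0.207. At an unadjusted p under 1e-09 the counts of bins were 2913 for H3K27me3, 20469 for H3K79me2 and 221 for RNA Pol II. With all reads as deposited they were 65808, 78953 and 105553. Against the surrounding 50 kb they were 1611, 5661 and 202. Thinned to the same number of reads, H3K27me3 gave 3899 and H3K79me2 22304 bins, which the lower depth accounts for by construction. H3K79me2 gave 30068 bins of 5 kb and 33881 at 5 times the mean or more. The 5 kb bins covered 150 Mb, against 60.1 Mb with 1 kb bins and 102 Mb as designed. For H3K27me3 the values were 61.1, 9.33 and 23.7 Mb, in the same order, so the extents depend on bin width. RNA Pol II gave 1776 against the median, 989 with both categories and 11405 with 1 read per position in each run and the runs summed. This last setting counts positions shared by both runs again. For the other changes the cause was not tested. The share of run bins was 73.9% with 5 kb bins, 57.4% with all reads and 79.1% when thinned. With a single run, RNA Pol II gave 488 to 613 bins, with ratios of 19.1 to 23.1 for H3K27me3 and 12.04 to 12.9 for H3K79me2. No paired analysis was possible because the marks share only replicate number 1. The planned gene alternatives were not run, for want of an hg18 annotation. The number of distinct reads limits RNA Pol II most, with 55% of simulated 8-fold bins recovered. From the positions that both runs shared, the library was estimated to hold 1731896 positions, of which the pooled runs covered 94.8%. The estimate assumes that both runs drew on the same library and that each position was equally likely to be drawn. By it, more sequencing of that library would add few positions.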

Other observations

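The tests of this part were set before the results they measure, except the comparison across chromosomes and windows. The marks differed between chromosomes. Without the bins enriched in all 3, H3K27me3 took its highest shares of usable bins on chromosome 17, with 1.77%, and chromosome 19, with 1.69%, and its lowest on chromosome 3, with 0.527%. H3K79me2 was highest on chromosome 17, with 5.66%, and lowest on chromosome 13, with 2.87%. RNA Pol II was highest on chromosome 19, with 0.146%. Over the 22 autosomes all 3 pairs of shares were correlated. For H3K27me3 and RNA Pol II Pearson's r was 0.733 and Spearman's rho 0.731 (permutation p = 0.00016 and 0.00029, adjusted over 3 pairs 0.00048 and 0.00087), with r of 0.590 without chromosomes 17 and 19. For H3K27me3 and H3K79me2 they were 0.693 and 0.680 (permutation p = 0.00035 and 0.00067, adjusted 0.000525 and 0.00100), with r of 0.614 without the same chromosomes. For H3K79me2 and RNA Pol II they were 0.436 and 0.583 (permutation p = 0.0414 and 0.00506, adjusted to the same values), with r of 0.393 without chromosomes 17 and 22. Over 2543 windows of 1 Mb, which are not independent, distinct reads per usable bin were compared instead of shares, with all bins kept. For the same pairs, in that order, r was -0.326, -0.121 and 0.249. The measure differs from the shares, so the change of sign cannot be put down to scale alone.

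A hypothesis was that the end of an H3K79me2 region with more of the mark is the start of the transcribed unit, so that RNA Pol II would be higher there. In 3294 regions of at least 10 kb, the edge bin on the side with more H3K79me2 held 1.36 times (1.30 to 1.42) the RNA Pol II reads of the other edge bin, 7841 against 5757. H3K27me3 at the same edges gave 1.14 (1.095 to 1.19), so a part of the ratio may come from how readily sequence at that edge is read in any library.

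A further hypothesis was that H3K27me3 regions border H3K79me2 regions. It was not borne out: 239 of 6262 H3K27me3 regions, 3.82%, had their highest bin within 10 kb of an H3K79me2 bin, where 100 circular shifts gave 702 to 901.

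The 38 bins enriched for H3K27me3 and RNA Pol II but not for H3K79me2 might be taken for places that carry a repressive mark and the polymerase together. They held 103.5 times as many positions of the second read category as other H3K27me3 bins, with a mean of 36.7 against 0.355, and 31 of the 38 held at least 1. If the second category holds reads that align to more than 1 place, which is assumed here and not stated in the sources used, reads from repeated sequence may account for them. Of these bins, 23 of the 38 lay within 1 Mb of a run of at least 100 kb without reads.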
